A study of Mus musculus with 3 samples.

How the data were processed

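The transcriptomes of single CD3+ mouse T cells were measured in 3 droplet libraries made with the 10x Genomics protocol, 1 library per group. Per the labels, the T cells came from the surroundings of cancer cells that were wild type for Mal2 (WT), overexpressed Mal2 (OE) or had Mal2 reduced (KD). The title and description of the KD sample speak of a knockdown, whereas its genotype field and the design text speak of a knockout. The growth protocol names the mouse lines EO771 and 4T1 and the human line MDA-MB-468, all of triple-negative breast cancer, and does not tie any of them to these libraries. Per the submitters' processing notes, Cell Ranger and the mm10 genome were used. The versions, the annotation and the filters on cells are not given in the sources used here.

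The deposited table held 17629 genes and 27827 cells, with natural log values. From the values themselves, each entry was the natural log of 1 plus the UMIs per 10000 UMIs of the cell, minus 1 constant per library, with results at or below 0 written as 0. The constants were 0.127 in WT, 0.139 in OE and 0.178 in KD, and no label explains them. Adding each constant back and scaling each cell gave whole UMI counts for 100% of the values above 0, to within 0.001 UMI. In 6 WT, 6 OE and 307 KD cells the subtraction had set genes with 1 UMI to 0, which was 3.98% of the KD cells and lost 0.325% of the KD UMIs. The design had foreseen both counts and log values, and the recovered UMIs were used throughout. Of the genes, 150 had no UMI in any cell.

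Recovered UMIs totalled 178477731 in WT, 53589507 in OE and 188871571 in KD. The median cell had 14851 UMIs and 3210 genes in WT, 4720 UMIs and 1689 genes in OE, and 22484 UMIs and 4048 genes in KD. Every cell had at least 509 genes and under 10% mitochondrial UMIs. The planned filter of 500 genes and 10% mitochondrial UMIs therefore removed 0 cells and tested nothing. The scrublet doublet caller in scanpy 1.11.5 called 1 WT, 2 OE and 0 KD cells and was judged not to have worked. All cells were kept, and the 6% of cells with the highest scores in each library were left out in an alternative.

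Cells were clustered on 2000 variable genes, 30 principal components and a graph of shared neighbours with 20 neighbours per cell, computed with numpy and scipy. Clusters came from the Leiden algorithm (igraph 0.11.9, leidenalg 0.10.2) at resolution 1.0, with no integration across libraries. The 27 clusters were named from fixed markers. The thresholds that turn markers into names were set after the clusters had been seen. CD8 T-like clusters had Cd8a or Cd8b1 in at least 75% and Cd4 in at most 10% of cells. CD4 T-like clusters had Cd4 in at least 40% of cells and 1.5 times as often as Cd8a or Cd8b1. For both, no other cell type could have more of its markers among the 10 leading genes of the cluster. This kept cluster 8, with Cd8a or Cd8b1 in 76.2% of cells but led by natural killer genes, among the unresolved clusters. Proliferating clusters were kept as a class of their own, and T-like clusters that met no rule were called unresolved. Cells of OE lay mostly in clusters of their own, while WT and KD shared several, so a class of 1 name came from different clusters in OE and only in part in WT and KD. CD4 T-like cells below are conventional CD4 and regulatory T-like cells together.

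UMIs were summed per library and class and expressed as CPM with exact Poisson 95% intervals. Shares of cells were given exact Clopper-Pearson 95% intervals. All these intervals cover counting error only. With 1 library per group there was no test across samples and no replicate check, since cells are not replicates. Ratios of levels are CPM ratios, and log2 ratios were computed on CPM + 5, which understates the change of low genes. A size rule replaced a test. It asked for a log2 ratio of at least 1 in size among genes detected in at least 10% of the cells of either library. The named genes followed a fixed rule. It took the 10 largest increases and the 10 largest decreases per comparison and class, without T-cell receptor variable, immunoglobulin and haemoglobin genes and clone names, together with members of fixed gene lists.

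The fixed lists covered T core, cytotoxic, inhibitory receptor, naive and memory, activation, regulatory T, interferon response, proliferation, MHC class I presentation, MHC class II presentation, T helper 1, T helper 2, T helper 17, dissociation and stress, hypoxia and glycolysis, oxidative phosphorylation, ribosomal protein and mitochondrial genome genes. A member counted as measured at 5 CPM or more in either library. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a p-value.

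The steps were tested on simulated data with 200 changed genes per comparison drawn at the real levels and depths. All recovered counts equalled the simulated counts, which had been turned into log values by the same formula that the recovery assumes. None of the unchanged genes passed the size rule (0 of 7537 for OE against WT, 0 of 7999 for KD against WT and 0 of 8066 for KD against OE). These draws held counting error only, with no variation between cells or libraries. They therefore do not show how often genes pass between 2 real libraries without a change in Mal2. Of 50 genes changed 3-fold, 94% passed for OE against WT, 92% for KD against WT and 80% for KD against OE. Of 50 genes changed 1.5-fold, 0% passed in each comparison. Gene positions were taken from the GENCODE annotation of GRCm38, the assembly also called mm10.

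The markers, gene lists, rule for named genes and the following alternatives were fixed before the data were examined. The alternatives were a higher clustering resolution of 1.5, clustering without T-cell receptor, ribosomal, mitochondrial and proliferation genes, and classes from marker detection per cell. Others were scaling to the median gene, thinning each cell to 2000 UMIs, pseudocounts of 1 and 25 CPM, detection in 5% of cells or no detection filter, and a size threshold 1.5 times larger. Thinning left out 101 WT, 447 OE and 16 KD cells below 2000 UMIs. In all, 11 planned settings were run and 10 were added after the data had been seen. The added ones left out cells with high doublet scores, cells that had lost genes with 1 UMI, the proliferating clusters, or the clusters led by interferon genes. They also counted proliferating CD8 clusters, cluster 8, or clusters 8 and 13 as CD8 T-like, left out cluster 19, led by cytotoxic genes, or kept cells in bands of equal UMIs, for lists, gene numbers and named genes. Thinned counts of genes past the size rule were likewise added later. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.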

Results

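The series profiled T cells that had been in the surroundings of breast cancer cells, to ask how the level of Mal2 in the cancer cells bears on those T cells. Mal2 encodes a small transmembrane protein of the MAL family that takes part in membrane trafficking. It was altered in the cancer cells and not in the T cells, so its level in T cells would not check the labels, and it was not analysed here. There were 3 libraries of CD3+ mouse T cells, 1 each from wild-type (WT), Mal2-overexpressing (OE) and Mal2-reduced (KD) surroundings. They held 10609, 9505 and 7713 cells, and the median cell had 14851 UMIs in WT, 4720 in OE and 22484 in KD. Because each group was 1 library, no difference below has a replicate check. "Higher" and "lower" describe these libraries, and intervals are 95% intervals for counting error.

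Several of the genes named below lie at these positions on GRCm38, each a protein-coding gene. Gzmb spans 56258838 to 56262260 on chromosome 14, and Ifng spans 118441046 to 118445892 on chromosome 10. Il2ra spans 11642807 to 11693193 on chromosome 2, and Lag3 spans 124904361 to 124911705 on chromosome 6. Klf2 spans 72319033 to 72321656 on chromosome 8, and S1pr1 spans 115710433 to 115715072 on chromosome 3. Slc2a1 spans 119108711 to 119137983 on chromosome 4, and Pkm spans 59656368 to 59679375 on chromosome 9. Ms4a4b spans 11443553 to 11467055 on chromosome 19, and Ltb spans 35194439 to 35196320 on chromosome 17.

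Conventional CD4 T-like cells made up more of the T-like cells in OE than in the other libraries. Their share was 38.1% (37.2 to 39.1) in OE, 19.7% (18.9 to 20.4) in WT and 26.6% (25.6 to 27.6) in KD. Regulatory T-like cells, named by Foxp3 and its companions, made up 10.8% (10.2 to 11.5) in OE, 4.89% (4.49 to 5.32) in WT and 7.199% (6.63 to 7.80) in KD. CD8 T-like cells made up 25.9% (24.98 to 26.75) in OE, 39.8% (38.8 to 40.7) in WT and 31.3% (30.2 to 32.3) in KD. Gamma-delta T-like cells made up 2.995% (2.66 to 3.36) in OE, 0.340% (0.238 to 0.470) in WT and 0.443% (0.307 to 0.619) in KD.

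**Figure D1:**
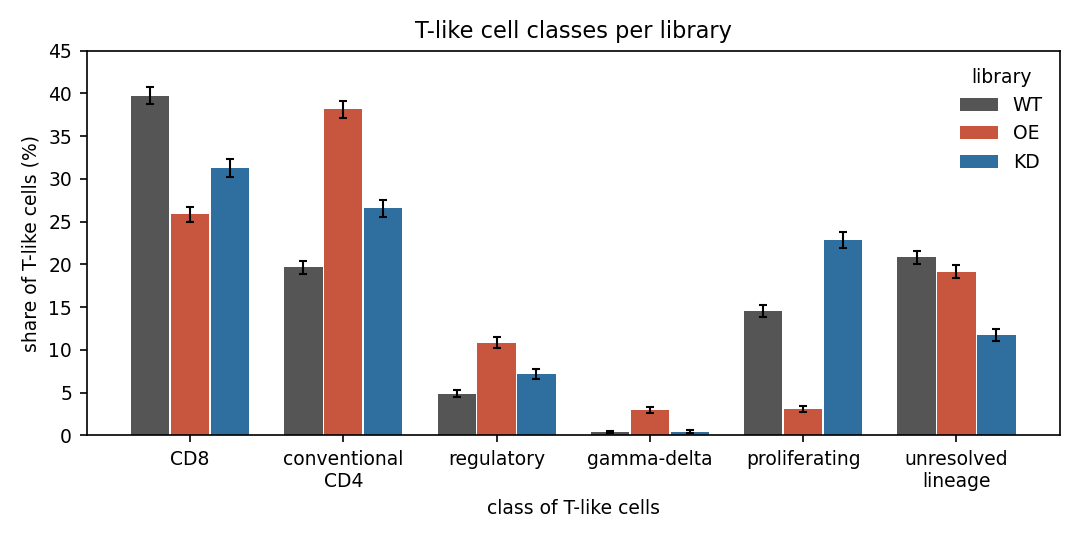
Share of T-like cells (%) in each class, for WT, OE and KD, with exact 95% intervals for counting error as error bars. The conventional CD4 bar is at 38.1% in OE against 19.7% in WT, and the CD8 bar is at 25.9% against 39.8%.

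The CD8 shares rested on which clusters were counted. Proliferating clusters, kept out of the other classes, held 14.5% of the T-like cells in WT, 3.03% in OE and 22.8% in KD. With the proliferating CD8 clusters counted as CD8 T-like, the CD8 share was 51.1% in WT, 25.9% in OE and 51.4% in KD. With classes taken from marker detection in each cell it was 62.0%, 37.6% and 59.1%, and conventional CD4 cells were at 12.6%, 23.5% and 14.3%. Those classes call a cell CD4 only if it has no Cd8a or Cd8b1 UMI, and so depend on UMIs per cell. Among CD4 T-like cells, Cd8b1 was found in 20.6% in WT, 8.65% in OE and 29.0% in KD at full depth. After thinning these were 4.89%, 5.32% and 6.46%. With cluster 8, which carries Cd8a or Cd8b1 but is led by natural killer genes, counted as CD8 T-like, the CD8 share was 50.5% in WT, 25.87% in OE and 36.2% in KD. A further 20.8% of T-like cells in WT, 19.2% in OE and 11.7% in KD had no resolved lineage. Cells of OE lay mostly in clusters of their own, while WT and KD shared several. CD8 T-like cells lay mostly in clusters 0 and 6 in WT, 2 and 19 in OE and 3 in KD, with 398 and 182 KD cells in clusters 0 and 6. Conventional CD4 cells lay mostly in cluster 1 in WT, in 5, 9 and 17 in OE and in 4 in KD, with 324 KD cells in cluster 1 and 140 WT cells in cluster 4. Regulatory cells lay mostly in 12 in WT and KD and in 14 in OE.

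T-like cells of the OE library had far lower levels of Gzmb, Il2ra and the glycolysis genes than those of the WT library, and higher levels of Klf2, S1pr1 and most naive and memory genes. The cytotoxic and activation lists as wholes went both ways. Gzmb, which encodes the cytotoxic protease granzyme B, was at 18.8 CPM (17.7 to 20.04) in OE and 1227 CPM (1221 to 1232) in WT, 65.1-fold lower (61.2 to 69.4). Il2ra, the alpha chain of the interleukin 2 receptor, was at 20.3 CPM in OE and 344 CPM in WT, 16.98-fold lower (15.98 to 18.06). Klf2, a transcription factor of quiescent T cells, was 27.5-fold higher in OE (26.9 to 28.2), at 1051 against 38.2 CPM. S1pr1, a receptor that T cells need to leave lymphoid organs, was at 247 CPM in OE and 7.59 CPM in WT. In cells of 6000 to 12000 UMIs the ratios of Klf2 (993 against 94.3 CPM), S1pr1 (221 against 17.2) and Gzmb (15.5 against 690) were smaller, and that of Il2ra (17.2 against 305) was not. There all 20 named genes of this comparison kept their direction past the size rule, and 9 moved by more than 1.5-fold. In cells of 3000 to 6000 UMIs all 20 did so too, and 14 moved by that much. In that band Klf2 was at 1252 against 208 CPM and Ccl5 at 1865 against 613. At 12000 to 24000 UMIs Gzmb was at 63.4 CPM in OE and 1176 in WT.

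Examples within the gene lists below were chosen after their values were seen. In OE against WT, 1672 of 7737 measured genes passed the size rule, 899 higher and 773 lower. The share higher was 53.8%, and it turned to 47.3% when the median gene was set to no change. This is a description of size in 2 libraries and not a count of tested changes. Beside Klf2 and S1pr1, the largest increases were in S100a4 (394 against 2.04 CPM), the chemokine gene Ccl5 (1954 against 56.4) and the heat shock gene Hspa1b (129.8 against 0.320). They were followed by the integrin gene Itga4 (258 against 10.9), Cd7 (a log2 ratio of 3.97), Ifi203 (348 against 18.0), Fos (118 against 3.17) and Klf3 (209 against 10.5). Beside Gzmb and Il2ra, the largest decreases were in Asns, which makes asparagine (1.56 against 202 CPM), the translation regulator Eif4ebp1 (15.4 against 426), Batf3 (0.817 against 108) and Cth. Cth had no UMI in OE, which allows up to 0.0701 CPM, and 73.7 CPM in WT. Irf4, a transcription factor of activated T cells, followed with 5.59 against 157 CPM, then Lta (11.1 against 215), the serine synthesis gene Psat1 (19.1 against 269) and the chemokine gene Ccl4 (12.9 against 197). The count was 948 when each cell was thinned to 2000 UMIs, 624 in cells of 3000 to 6000 UMIs and 1031 in cells of 6000 to 12000 UMIs. Fewer genes reach detection in 10% of cells at low UMIs, with 5143 measured in cells of 3000 to 6000 UMIs. Part of such drops, here and below, can therefore come from that filter and not from smaller differences.

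**Figure D2:**
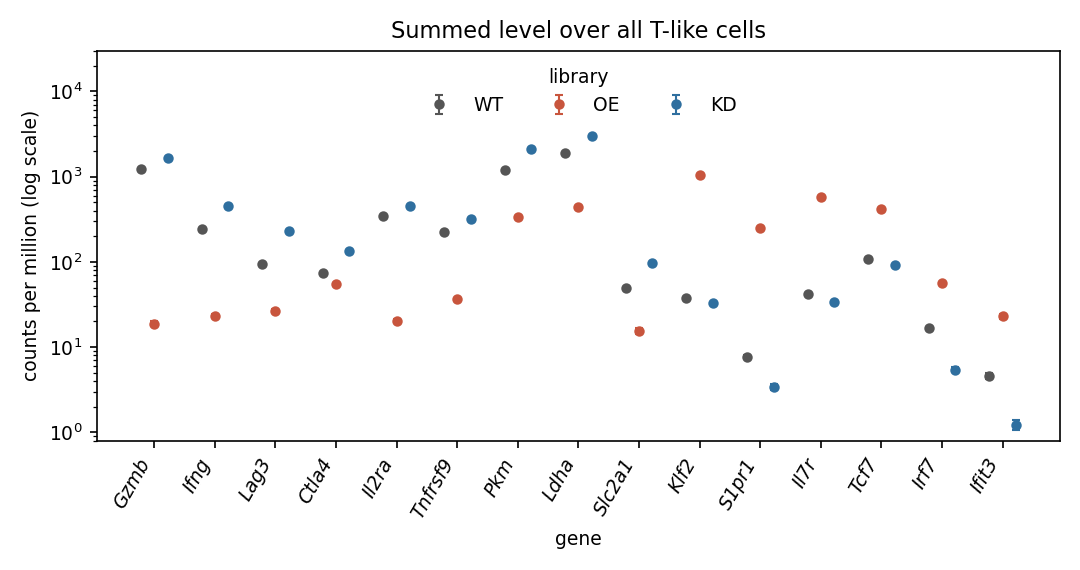
Summed level in CPM (log scale) of 15 genes over all T-like cells of the WT, OE and KD libraries, with exact Poisson 95% intervals, mostly smaller than the points. Gzmb is at 18.8 in OE against 1227 in WT and 1667 in KD, and Klf2 is at 1051 in OE against 38.2 and 32.5.

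All 12 measured genes of the hypoxia and glycolysis list passed the size rule as lower in OE than in WT, with a median log2 ratio of -1.93, at percentile 0 of the random lists. The lactate dehydrogenase gene Ldha was at 442.5 CPM in OE and 1872 in WT, the triosephosphate isomerase gene Tpi1 at 63.7 and 629, and the glucose transporter gene Slc2a1 at 15.5 and 49.5. Of 13 oxidative phosphorylation genes, 3 were lower past the rule and 10 lay between, with a median of -0.52 that was -0.26 in cells of 6000 to 12000 UMIs and -0.01 at 12000 to 24000. In the naive and memory list 8 of 12 genes were higher past the rule and 0 lower, with a median of 1.45 and percentile 100, or 0.98 in cells of 3000 to 6000 UMIs. Il7r, the interleukin 7 receptor, was at 582 CPM in OE and 41.5 in WT, and the transcription factor gene Tcf7 at 419 and 109. Of 14 activation genes 5 were higher and 4 lower, with Cxcr3 at 126 against 19.3 CPM and Tnfrsf9 at 36.3 against 223. Their median of 0.36 turned to -0.12 in CD8 and -0.28 in CD4 T-like cells, and to -0.14 in cells of 3000 to 6000 UMIs. In the T core list, 5 of 10 genes were higher and none lower (median 1.02, and 0.56 in cells of 6000 to 12000 UMIs), among them Cd3g at 1138 against 387 CPM.

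The dissociation and stress list was also higher in OE than in WT, with 8 of 15 genes higher past the rule, 3 lower and a median of 1.23. In bands of equal UMIs that median lay between 0.36 and 0.88. Jun was at 344 CPM in OE and 41.5 in WT, and Fosb at 48.3 and 0.960. Within the same list, Atf3 was at 0.190 CPM in OE and 48.9 in WT, and Hsp90aa1 at 334 and 1255. Of the 19 measured interferon response genes, 10 were higher and 3 lower, with a median of 1.01. Irf7, a regulator of interferon genes, was at 56.2 CPM in OE and 16.7 in WT, and Ifit3 at 22.9 and 4.58. Gbp2 went the other way, at 38.7 against 348 CPM. The interferon median was 0.25 in cells of 6000 to 12000 UMIs and turned to -0.72 in cells of 3000 to 6000 UMIs. Within classes it was -0.09 in CD8 and 0.38 in CD4 T-like cells.

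The proliferation list had 2 genes higher, 7 lower and a median of -0.54 in OE against WT, with Mcm3 at 53.4 against 260 CPM and Pcna at 51.6 against 111. Its direction also depended on UMIs per cell. The median was -0.76 in cells of 3000 to 6000 UMIs, 0.58 at 6000 to 12000 and 2.24 at 12000 to 24000, and -1.03 after thinning. The last band held 349 cells of OE and 4129 of WT. Proliferating cluster 18 held 277 OE cells with a median of 15360 UMIs. The WT cells of proliferating clusters 10 and 15 had medians of 30610 and 30410. A band thus takes in different shares of proliferating cells from each library. Within classes it was -1.76 in CD8 and -1.37 in CD4 T-like cells. Of 14 MHC class I presentation genes, 3 were higher and 1 lower (median 0.24). H2-K1 was at 2879 CPM in OE and 1372 in WT, H2-D1 at 2254 and 1043, and the chaperone gene Calr at 219 and 499.8. That median was -0.12 in cells of 6000 to 12000 UMIs. In the MHC class II presentation list 2 genes were measured, too few for a median.

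Over all T-like cells, the cytotoxic list went both ways in OE against WT, with 8 of 16 genes higher, 4 lower and a median of 0.82 against a mean of -0.05. Nkg7 was at 501 CPM in OE and 228 in WT, while Ifng, the main cytokine of type 1 immunity, was at 23.1 and 245. Ifng was the leading gene of cluster 7, of unresolved lineage, which held 1048 cells of WT and 1 of OE. Within classes it was at 7.73 against 17.4 CPM in CD8 and, the other way, at 28.6 against 5.05 in CD4 T-like cells. The cytotoxic median was -0.36 in cells of 3000 to 6000 UMIs. Of 11 inhibitory receptor genes 4 were higher and 2 lower (median 0.80, and 0.05 in cells of 3000 to 6000 UMIs), with Tox at 104 against 12.4 CPM and Lag3 at 26.8 against 95.3. Of 9 regulatory T genes, 3 were higher and 3 lower, with Ikzf2 at 242 against 52.4 CPM. Their median of -0.41 was -1.46 in cells of 3000 to 6000 UMIs, -0.85 at 6000 to 12000 and turned to 0.24 at 12000 to 24000. The T helper 1 list had a median of -0.91 (-0.50 in cells of 12000 to 24000 UMIs), with Il12rb2 at 2.05 against 44.6 CPM and Stat4 at 105 against 30.9. The 3 measured T helper 17 genes were all higher (median 1.17, and 0.69 (4 measured) in cells of 3000 to 6000 UMIs), among them Rora at 46.2 against 9.003 CPM. Ribosomal protein genes had a median of -0.17 and mitochondrial genome genes 0.47.

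CD8 T-like cells showed the contrast between OE and WT within 1 lineage, with 1702 of 7267 measured genes past the size rule. Ccl5 was at 2314 CPM in OE and 12.9 in WT, 179.5-fold higher (167 to 193). Klrd1, which encodes CD94, was at 364 against 7.94 CPM, Il7r at 780 against 29.5 and Tmem71 at 114 against 4.17. With cluster 8 counted as CD8 T-like, WT was at 50.06 for Ccl5 and 89.35 for Klrd1, and without cluster 19 OE was at 154.3 for Ccl5 and 351 for Klrd1. Gzmb was at 19.5 CPM in OE and 1255 in WT, and Il2ra at 2.28 and 268. Irf8 (6.92 against 232 CPM), Cish (3.17 against 157), Chchd10 (24.9 against 474) and Ly6a (85.9 against 1388) were also among the 10 largest decreases. The number was 958 after thinning and 1034 in cells of 6000 to 12000 UMIs.

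The direction of the cytotoxic list between OE and WT in CD8 T-like cells depended on which clusters were counted. As classed, 9 of 15 measured genes were higher in OE and 4 lower, with a median of 1.57 (1.37 to 1.60). With cluster 8, which held 1143 cells of WT and 1 of OE, counted as CD8 T-like, the median turned to -0.53. With cluster 13 counted as well, which is also led by natural killer genes, carries Cd8a or Cd8b1 in 61.9% of cells and held 1032 cells of OE and 2 of WT, it was 0.96. Without cluster 19, led by Gzmk, Ccl5 and Gzma, which held 238 of the OE cells and none of WT, it turned to -0.76. That is a median over fewer genes, since Gzma, Gzmk, Klrk1 and Klrc1 then lay below 5 CPM in both libraries. Prf1, Nkg7, Ccl5, Klrd1 and Ctsw were still higher in OE there, and Gzmb, Ifng, Tnf, Ccl3, Ccl4 and Cst7 lower. As classed, Gzma was at 92.5 against 2.25 CPM, the perforin gene Prf1 at 38.7 against 5.80 and Gzmk at 23.4 against 0.163. With cluster 8, WT was at 32.1 for Gzma, 10.8 for Prf1 and 0.224 for Gzmk. With cluster 8 in and 13 out, only WT and KD gain such cells. Without cluster 19, OE was at 1.70 for Gzma, 31.5 for Prf1 and 0.268 for Gzmk, so Gzma and Gzmk were high in OE only through that cluster. Gzmb and the chemokine genes Ccl3 (4.07 against 18.2) and Ccl4 (15.4 against 68.5) were lower. Without cluster 19 they were lower still in OE, at 3.925 CPM for Gzmb, 0.268 for Ccl3 and 0.714 for Ccl4. The naive and memory list had 7 of 11 genes higher and none lower, with a median of 2.02. Lef1 was at 579.5 against 139 CPM. The inhibitory receptor list had 1 of 7 genes higher and 3 lower, with a median of -0.64 (-1.42 to -0.08). Lag3 was at 5.70 against 115 CPM, Ctla4 at 7.57 against 63.4 and Tox at 56.4 against 12.9. With classes taken from marker detection the cytotoxic median was 0.77 and the inhibitory receptor median turned to 0.35, and with clusters 8 and 13 counted it turned to 0.17. In cells of 3000 to 6000 UMIs the naive and memory median was 0.89 and the inhibitory receptor median -1.10.

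In CD4 T-like cells, conventional and regulatory together, 1834 of 7355 measured genes passed the size rule in OE against WT, 58.9% of them higher. S100a4 was at 552 against 0.995 CPM, S100a6 at 824 against 8.38, Ifi203 at 365 against 7.15 and Ahnak at 199 against 6.44. The largest decreases included Irf4 (7.58 against 228 CPM), Gbp2 (38.4 against 663), the metallothionein gene Mt1 (3.19 against 109) and Tpi1 (55.2 against 691.5). The inhibitory receptor list was higher here, with 6 of 11 genes higher, 1 lower and a median of 1.17, or 0.75 in cells of 6000 to 12000 UMIs. Pdcd1, which encodes PD-1, was at 68.5 CPM in OE and 7.51 in WT, and Tox at 153 and 16.2. The median of all genes lay 0.14 above 0, and scaling to it turned the split to 46.8% higher.

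**Figure D3:**
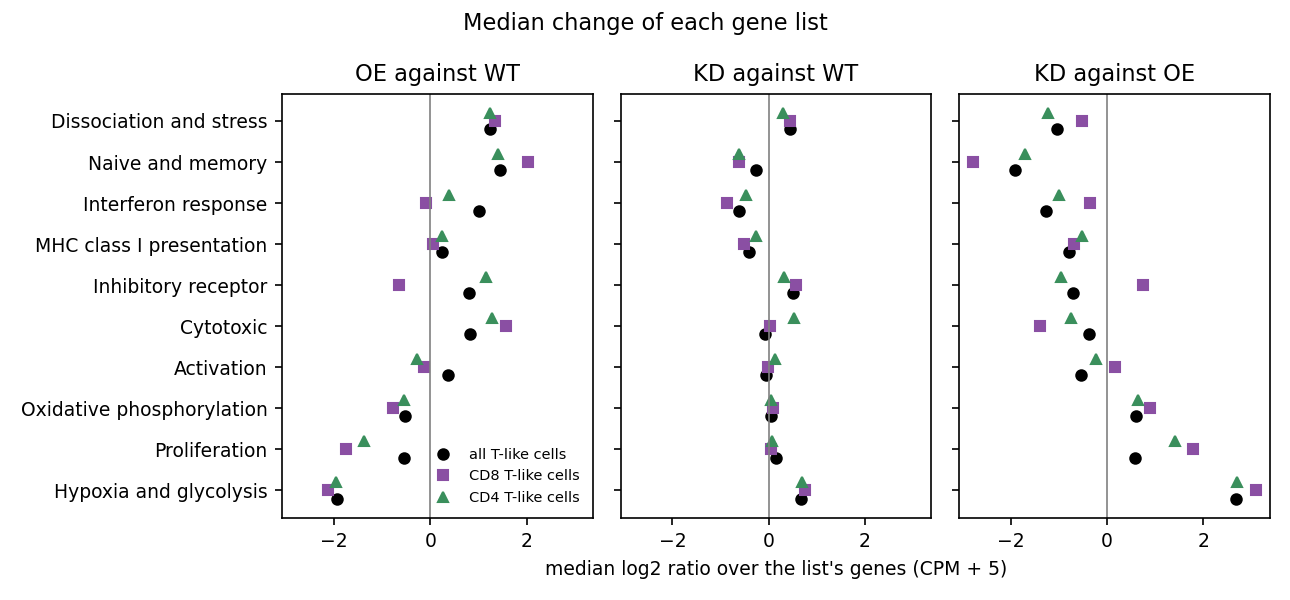
Median log2 ratio (CPM + 5) of 10 gene lists for OE against WT, KD against WT and KD against OE, in all, CD8 and CD4 T-like cells. In all T-like cells the hypoxia and glycolysis list is at -1.93 in OE and 0.66 in KD, both against WT. The CD8 points of the cytotoxic list turn when cluster 8 is counted as CD8 T-like, to -0.53, -0.18 and 0.05. Those against OE also turn without cluster 19, over fewer measured genes.

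T-like cells of the KD library differed from those of the WT library by far less than those of OE did. Over all cells, the 12 hypoxia and glycolysis genes lay above 0 and the 13 measured interferon response genes below it, mostly by less than the size rule. The executioner caspase gene Casp6 was at 166.5 CPM (165 to 168) in KD and 39.97 CPM (39.05 to 40.9) in WT, 4.17-fold higher (4.06 to 4.27). Lag3, an inhibitory receptor of activated T cells, was at 227.5 CPM in KD and 95.3 in WT, and Ifng at 454 and 245, though at 23.2 and 17.4 in CD8 T-like cells. Ms4a4b, a membrane protein gene of T cells, was at 94.8 CPM (93.4 to 96.2) in KD and 395 CPM (392 to 398) in WT, 4.17-fold lower (4.10 to 4.24). Ltb, which encodes lymphotoxin beta, was at 160.4 CPM in KD and 412 in WT. It was below the size rule in cells of equal UMIs, at 861 against 1088 CPM in cells of 3000 to 6000 UMIs, 480 against 733 at 6000 to 12000 and 205.5 against 395.5 at 12000 to 24000. Of the 20 named genes of this comparison, 12, 16 and 19 passed the rule in these 3 bands, and all kept their direction.

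In KD against WT, 64 of 8199 measured genes passed the size rule, 24 higher and 40 lower. Beside Casp6, the largest increases were in the cytokine gene Il21 (38.2 against 7.13 CPM), Fosb (15.8 against 0.960), Ajuba (19.9 against 2.88), Fos (20.01 against 3.17) and Tnip3 (63.7 against 17.8). They were followed by Crabp2 (14.9 against 1.84), the oxygen-sensing hydroxylase gene Egln3 (107.5 against 36.9), Gzma (59.4 against 19.0) and the lactate exporter gene Slc16a3 (100.1 against 34.6). Beside Ms4a4b and Ltb, the largest decreases were in Ms4a4c (11.6 against 49.2 CPM), Mid1 (1.94 against 15.6), Ncoa7 (17.5 against 55.5), Mndal (10.4 against 36.2), the microRNA host gene Mir155hg (13.4 against 43.1), Epsti1 (17.7 against 53.9), Lta (81.1 against 215) and Trim12c (15.8 against 47.9). The number of genes moved with the settings, to 32 after thinning, 122 in cells of 3000 to 6000 UMIs, 112 in cells of 6000 to 12000 UMIs, 127 with a pseudocount of 1 and 14 with a pseudocount of 25.

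All 12 genes of the hypoxia and glycolysis list were above 0 in KD against WT, with 1 past the size rule and a median of 0.66 at percentile 100. Slc2a1 was at 95.7 CPM in KD and 49.5 in WT, the pyruvate kinase gene Pkm at 2122 and 1184, and Ldha at 2995 and 1872. Bnip3, a hypoxia-induced mitophagy gene, was at 86.0 and 33.9 CPM. Over 4 bands of equal UMIs, chosen after the data were seen, the median ran from 0.55 in cells of 24000 to 48000 UMIs to 1.03 in cells of 3000 to 6000 UMIs. The 13 oxidative phosphorylation genes had a median of 0.06 with none past the rule.

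None of the 13 measured interferon response genes was above 0 in KD against WT, and 3 were lower past the size rule, with a median of -0.62 (-0.64 to -0.61) at percentile 0. Irf7 was at 5.43 CPM in KD and 16.7 in WT, and Rtp4 at 2.70 and 13.1. In bands of equal UMIs that median was 0.01 in cells of 3000 to 6000 UMIs and -0.30, -0.27 and -0.39 in the bands above. Without the clusters led by interferon genes it was -0.50. Of 14 MHC class I presentation genes, 12 were below 0 in KD and none passed the rule (median -0.42). The immunoproteasome gene Psmb8 was at 583 CPM in KD and 897 in WT, and B2m at 1195 and 1463, while Calr was at 793 and 499.8. This median was 0.13 in cells of 3000 to 6000 UMIs and -0.04 in cells of 6000 to 12000.

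**Figure D4:**
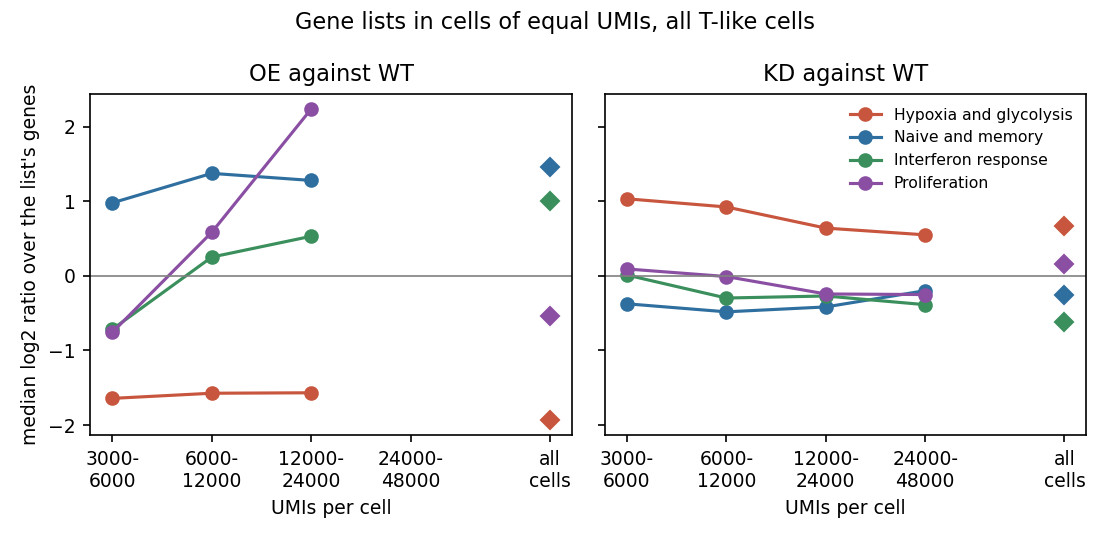
Median log2 ratio of 4 gene lists in all T-like cells, within bands of equal UMIs per cell (x axis) and over all cells, for OE against WT and KD against WT. The hypoxia and glycolysis list keeps its sign in each band, while the interferon response list in OE against WT runs from -0.72 at 3000 to 6000 UMIs to 0.53 at 12000 to 24000.

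The inhibitory receptor list had 7 of 8 genes above 0 in KD against WT, 1 of them past the size rule (Lag3), and a median of 0.50 (0.79 in cells of 6000 to 12000 UMIs), with Ctla4 at 135 CPM in KD and 73.9 in WT. The naive and memory list had a median of -0.26 (-0.48 in cells of 6000 to 12000 UMIs), with Ccr7 at 166 against 318 CPM and Slamf6 at 19.97 against 45.2. The 3 measured T helper 2 genes were all above 0 (median 1.20), with Gata3 at 83.5 against 41.3 CPM, Il4 at 22.3 against 4.85 and Il13 at 39.2 against 14.2. Of the 3 measured T helper 17 genes, Il17a was at 21.7 against 3.45 CPM and Il17f at 6.67 against 0.556, while Rora was not higher, at 8.96 against 9.003 (median 1.07, from 0.68 to 1.83 in bands of equal UMIs). Il17a was among the leading genes of cluster 25, of gamma-delta T-like cells, with 35 cells of WT and 33 of KD. The dissociation and stress list had 2 of 13 genes higher past the rule (Fos and Fosb) and a median of 0.44, or 0.73 in cells of 3000 to 6000 UMIs. The regulatory T median was 0.30, and 0.92 in cells of 6000 to 12000 UMIs. The 3 measured MHC class II presentation genes had a median of -0.44, which turned to 0.31 in that band and was 1.24 (4 measured) in cells of 3000 to 6000 UMIs. The other medians in KD against WT were 0.16 for proliferation, 0.13 for T helper 1, 0.01 for T core, -0.02 for mitochondrial genome, -0.05 for activation, -0.08 for cytotoxic, and -0.11 for ribosomal protein genes. The proliferation median was 0.09, -0.01, -0.24 and -0.25 in the 4 bands of rising UMIs, and the activation median was 0.23 in cells of 6000 to 12000. In cells of 3000 to 6000 UMIs the T helper 1 median was -0.46, and the cytotoxic median was -0.45 at 12000 to 24000.

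In CD8 T-like cells 96 of 7884 measured genes passed the size rule in KD against WT, 39.6% of them higher, or 28.3% after scaling to the median gene. Gzma was at 31.4 CPM in KD and 2.25 in WT, the ligand-activated transcription factor gene Ahr at 32.3 and 6.46, and Ccl4 at 221 and 68.5. Eomes, a transcription factor of effector and memory CD8 cells, was at 5.10 CPM in KD and 27.9 in WT, and Parp14 at 11.4 and 43.2. Gzmb was at 1247 and 1255 CPM. The cytotoxic list had 2 of 12 genes higher past the rule and a median of 0.04, which turned to -0.11 with classes from marker detection, to -0.02 with scaling to the median gene and to -0.18 with cluster 8 counted as CD8 T-like. With that cluster Gzma was at 86.3 against 32.1 CPM. The inhibitory receptor median was 0.56 (0.50 to 0.61), with Lag3 at 278 against 115 CPM. The naive and memory median was -0.61 (-0.65 to -0.57), with Lef1 at 79.9 against 139 CPM. In cells of 24000 to 48000 UMIs these medians were 0.29 and -0.26.

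In CD4 T-like cells 50 of 7704 measured genes passed the size rule in KD against WT, 28 higher and 22 lower. Il21 was at 91.0 CPM in KD and 20.7 in WT, Crabp2 at 16.6 and 0.968, and Frmd4b at 30.5 and 6.33. Sh2d1a, which encodes the adaptor SAP, was at 56.8 and 221 CPM, Pdcd4 at 50.1 and 119, and Ifit1 at 3.46 and 13.7. The hypoxia and glycolysis median was 0.69 in CD4 and 0.76 in CD8 T-like cells. The interferon response median was -0.48 and -0.86, or -0.24 and -0.28 in cells of 6000 to 12000 UMIs. The number of genes was 28 after thinning.

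The KD and OE libraries were the farthest apart, with 2195 of 8266 measured genes past the size rule, 1000 higher and 1195 lower in KD. The share higher was 45.6%, and it turned to 50.2% when the median gene was set to no change. Gzmb was 88.5-fold higher in KD (83.2 to 94.3), at 1667 against 18.8 CPM. In cells of equal UMIs it was at 806 against 15.5 CPM at 6000 to 12000 UMIs and 858.5 against 63.4 at 12000 to 24000. Ccl3, a chemokine gene of activated T cells, was at 157 against 3.46 CPM, the stress-induced transcription factor gene Atf3 at 86.6 against 0.190, and Pla2g12a at 327 against 12.7. S100a6 was at 21.6 CPM in KD and 730.3 in OE, and Smpdl3a at 3.75 and 178. In cells of 3000 to 6000 UMIs these were 262 against 624 and 38.1 against 200 CPM. There all 20 named genes of this comparison kept their direction past the size rule, and 14 moved by more than 1.5-fold. The hypoxia and glycolysis list had 12 of 12 genes higher in KD (median 2.69), and the naive and memory list had 9 of 12 lower and 1 higher (median -1.92). The interferon response list had 11 of 19 lower and 1 higher, with a median of -1.26. It turned to 0.73 in cells of 3000 to 6000 UMIs. The proliferation median was 0.59, and turned to -0.39 in cells of 6000 to 12000 UMIs and -2.81 at 12000 to 24000. That last band held 349 OE cells. Proliferating cells had a median of 15360 UMIs in OE cluster 18 and 36460 in KD cluster 11, so the bands differ in proliferating cells too.

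Within CD8 T-like cells, 2300 of 7955 genes passed the rule in KD against OE, and within CD4 T-like cells 2184 of 7800. Lag3 was at 278 CPM in KD and 5.70 in OE in the CD8 cells, and Tnfrsf4, which encodes OX40, at 216 and 6.83. In the CD4 cells Hemk1 was at 139 against 5.48 CPM, and Mndal at 5.93 against 311. The cytotoxic median in the CD8 cells was -1.40. It turned to 0.05 with cluster 8 counted as CD8 T-like and to 0.83 without cluster 19, and was -0.89 with clusters 8 and 13 counted. Without cluster 19, Gzmk, Klrk1 and Klrc1 lay below 5 CPM in both libraries and were no longer measured. As classed, the naive and memory median was -2.78 and the inhibitory receptor median 0.75. The inhibitory receptor median was 1.27 after thinning.

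Markers of most other cell types were higher in OE than in WT and KD. Some of these markers led T-like clusters of OE. They were Ccr9 (dendritic) in cluster 2, Epcam (tumour or epithelial) in cluster 16, and Klra7, Klre1 (natural killer) and Ly6c2 (macrophage) in cluster 13. Klra7 and Klre1 also led cluster 8, mostly of WT and KD. These sums therefore do not by themselves show other cell types or their RNA. Summed over its markers, the B cell list was at 315 CPM in OE, 97.8 in WT and 72.6 in KD, and the plasma cell list at 476, 138 and 121. Macrophage and monocyte markers summed to 247, 197 and 81.4 CPM, dendritic markers to 30.4, 2.02 and 1.27, endothelial markers to 66.2, 18.5 and 16.1, and natural killer markers to 78.5, 35.0 and 18.4. Erythroid markers summed to 7.75 CPM in OE and 0.0225 in WT, neutrophil markers to 2.24 and 0.174, and the 4 measured tumour or epithelial markers to 14.9 and 5.90. The 1 measured mast cell marker was at 0.0570 CPM in OE and at 0 in WT and KD. Fibroblast markers summed to 0.532 CPM in OE and 0.241 in WT. Clusters 23 and 26, led by genes of other cell types although all 8 T markers were detected in both, held 0.926% (0.743 to 1.14) of all cells in OE, 0.160% (0.0934 to 0.256) in WT and 0.583% (0.426 to 0.780) in KD. Immunoglobulin genes summed to 1721 CPM in T-like cells of OE, 119.8 in WT and 74.5 in KD.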

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

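Of the 9 tests of explanations below, 3 were written before their value was seen. The 6 chosen or amended after were, for the OE library, both tests on UMIs per cell, the test on the mix of classes, the test on handling and the test on free RNA, and, for glycolysis in KD, the test on handling or culture.

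Immunoglobulin RNA, which lies outside the gene lists compared between libraries, was found in T-like cells of the OE library above its level in the WT library. Igkc, the kappa light chain, was at 928.6 CPM in OE, 17.9 in WT and 5.60 in KD. Igha, the IgA heavy chain, was at 269 CPM in OE, 6.16 in WT and 0.0427 in KD, and Jchain, the joining chain, at 160.9, 0.680 and 0.0534. A cluster of macrophage and monocyte-like cells held 51 cells of the OE library and 0 of the WT and KD libraries. The 0 cells allow up to 0.0283% of cells in WT and 0.0389% in KD.

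Over all cells, 2 lists had medians of opposite sign in CD8 and CD4 T-like cells that were at least 0.25 in size in both, and none of these differences was tested. The inhibitory receptor list had a median of -0.64 in CD8 and 1.17 in CD4 T-like cells in OE against WT, and 0.75 and -0.95 in KD against OE. The T helper 1 list had a median of -0.82 in CD8 and 1.74 in CD4 T-like cells in OE against WT, and 1.15 and -0.50 in KD against OE. With classes taken from marker detection, the CD8 inhibitory receptor median in OE against WT was 0.35, and with clusters 8 and 13, led by natural killer genes, counted as CD8 T-like it was 0.17. In cells of 6000 to 12000 UMIs the T helper 1 medians in OE against WT had the same sign, 0.25 in CD8 and 1.28 in CD4. There the CD4 inhibitory receptor median in KD against OE was close to 0, at -0.012.

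The OE library stood apart from both others, with 1620 genes past the size rule against WT and against KD in the same direction, 868 higher and 752 lower. In cells of 6000 to 12000 UMIs, 2242 of OE and 2845 of WT, 99.81% of these genes kept their sign against WT. That argues against UMIs per cell as the only source of their direction in that band. The genes were picked by size in libraries that include these cells, which favours kept signs. In cells of 3000 to 6000 UMIs the interferon response, cytotoxic, activation and MHC class I medians turned sign, while all 20 named genes kept theirs. For size, UMIs per cell cannot be told apart from a change in the cells. Of the genes, 87.16% kept sign and size after thinning, short of the 90% bound written beforehand. In cells of matched UMIs 48.89% did, and the median gene kept 73.5% of its log2 ratio. A different mix of classes was argued against only by a measure added afterwards, the smallest median share of the log2 ratio kept within a class (88.71%); the bound written beforehand, 75% of genes, was missed in regulatory T-like cells at 69.38%, with 86.54% in CD8 and 90.93% in CD4. Handling before capture cannot be told apart from the change in Mal2, since each group was 1 library: the dissociation and stress median was 1.23, and the activation list, tried first, gave 0.36.

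The glycolysis and hypoxia list had a median of 0.66 in KD against WT, with 12 of 12 genes above 0 and 1 past the size rule. After thinning the median was 0.751, which met the bound written beforehand. Thinning at random keeps the expected proportions of genes within each cell, so it could hardly lower this median and cannot decide. In the bands of equal UMIs given above, chosen after the data were seen, the median stayed above 0 in each. That argues against a difference in UMIs per cell for the direction of the shift. A different mix of classes was argued against by the lowest median within 4 classes, 0.55. Handling or culture of the cells cannot be told apart from the change in Mal2 with 1 library per group. The oxidative phosphorylation list, at 0.0578, did not share the shift, and this leaves a pathway-specific effect of culture open.

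For the immunoglobulin RNA in OE, free RNA shared by all droplets would need similar levels in all classes. Only CD8, CD4 and regulatory T-like cells were compared, and among them the levels were similar. Igkc was at 710 CPM in CD8, 791 in CD4 and 758 in regulatory T-like cells, a highest over lowest ratio of 1.11. The mean Igkc UMIs per cell implied by the share of cells with one, at 2000 UMIs per cell, gave a ratio of 1.10. Over all T-like cells of OE the Igkc level was 928.6 CPM, above each of these classes. The classes left out were therefore higher together, so the comparison cannot decide on free RNA for all T-like cells. The test written first compared the shares themselves, 77.9%, 79.9% and 80.95%, which lie too near their ceiling to vary, and was set aside. Across all T-like cells of WT the share was 1.08%. Doublets with B or plasma cells cannot be told apart from free RNA for part of the signal. Of the Igkc UMIs, 32.98% sat in 312 of 9417 cells with 10 or more. The CD3+ selection does not settle this, since other cells were present after it. Cluster 23, led by Igkc, held 37 cells of OE, and cluster 26, led by macrophage genes, held 51. No biological explanation was tested.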

How the results depend on the processing

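The tests in cells of equal UMIs, for lists, gene numbers and named genes, without interferon-led clusters, without high doublet scores, without cells that had lost genes with 1 UMI, with proliferating cells moved or left out, with cluster 8 or clusters 8 and 13 counted as CD8 T-like, without cluster 19, and the thinned gene numbers were chosen only after the results were seen. Of 325 comparisons of 36 results with 1 setting changed, 192 stayed within their limits, 117 moved and 16 reversed. Those counted as reversed include changes of sign to values near 0. For the 180 named gene results 1 of 1640 comparisons reversed, 722 stayed within counting error and 917 moved. The filter on genes and mitochondrial share removed 0 cells and so tested nothing. No paired analysis was possible because each group was 1 library and nothing links cells across libraries. Below, the cause was not tested unless stated.

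Shares depended on how cells were classed. A higher clustering resolution gave 37.0% CD8 in WT, and 26.6% conventional CD4 in WT and 31.8% in KD. Clustering without T-cell receptor, ribosomal, mitochondrial and proliferation genes gave 45.95% CD8 in KD, and 22.6% conventional CD4 in WT and 29.0% in KD. Marker detection per cell gave CD8 shares of 62.0%, 37.6% and 59.1% in WT, OE and KD, regulatory shares of 7.03% in OE and 6.11% in KD, and conventional CD4 shares of 12.6%, 23.5% and 14.3%. Shares from marker detection depend on UMIs per cell, which differed between the libraries. Counting proliferating CD8 clusters as CD8 gave 51.1% in WT and 51.4% in KD, by construction, and counting cluster 8, led by natural killer genes, gave 50.5% and 36.2%.

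List medians below are given for OE against WT, KD against WT and KD against OE, as far as they moved. With marker classes, in CD8 T-like cells, the cytotoxic list was at 0.77, -0.11 (reversed) and -0.61, the naive and memory list at 1.87, -0.24 and -2.23, and the inhibitory receptor list at 0.35 (reversed) in OE against WT and 0.52 in KD against OE. With cluster 8 counted as CD8 T-like, the CD8 cytotoxic list was at -0.53, -0.18 and 0.052, reversed in each comparison by cells of that cluster, and the CD8 naive and memory list at 2.17 in OE against WT. That adds cells led by natural killer genes to WT and KD only, so cluster 13, which holds those of OE, was counted too. The CD8 cytotoxic list was then at 0.96, -0.18 (reversed) and -0.89, the inhibitory receptor list at 0.17 (reversed) in OE against WT and 0.60 in KD against OE, and the naive and memory list at 1.79 in OE against WT and -2.25 in KD against OE. Without cluster 19, the CD8 cytotoxic list was at -0.76 (reversed) in OE against WT and 0.83 (reversed) in KD against OE. Both came through cells of that cluster and are medians over fewer measured genes. The naive and memory list was then at 2.13 and -2.89. Scaled to the median gene, in KD against WT, the CD8 cytotoxic list was at -0.022 (reversed), the CD8 naive and memory list at -0.67 and the interferon response list at -0.65. In OE against WT the interferon response list was at 0.93 and proliferation at -0.62, and in KD against OE proliferation was at 0.64.

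After thinning to 2000 UMIs, the cytotoxic list in CD8 T-like cells was at 0.0087 in KD against WT, the inhibitory receptor list at 0.77 in KD against WT and 1.27 in KD against OE, and the naive and memory list at 1.84 in OE against WT and -0.66 in KD against WT. The interferon response list was at 0.70 in OE against WT and -1.13 in KD against OE, and proliferation at -1.03, 0.19 and 1.18. Without the highest doublet scores, the CD8 cytotoxic list in KD against WT was at 0.013. Without cells that had lost genes with 1 UMI, interferon in KD against WT was at -0.54 and proliferation at -0.57, 0.033 and 0.52. Without proliferating clusters, interferon was at 0.90 in OE against WT and -0.57 in KD against WT, and proliferation at -1.49, 0.10 and 1.49. Without interferon-led clusters, interferon was at 0.85, -0.50 and -1.01.

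In cells of 3000 to 6000 UMIs, in OE against WT, the CD8 cytotoxic list was at 1.21 and the CD8 naive and memory list at 0.89. The interferon response list was at -0.72, 0.010 and 0.73, reversed in OE against WT and KD against OE and near 0 in KD against WT. Proliferation was at -0.76, 0.092 and 0.86. This band held 982 T-like cells of WT and 5261 of OE. In cells of 6000 to 12000 UMIs, the CD8 cytotoxic list was at 1.24 in OE against WT and 0.0057 in KD against WT, the CD8 inhibitory receptor list at 0.82 in KD against WT and 1.43 in KD against OE, and the CD8 naive and memory list at 1.66, -0.66 and -2.52. The interferon response list was at 0.25, -0.30 and -0.44, and proliferation at 0.58, -0.010 and -0.39. The proliferation medians were reversed in OE against WT and KD against OE, and near 0 in KD against WT. The 1 named gene counted as reversed was Ccl4 in CD4 T-like cells in KD against WT, at 19.4 against 21.01 CPM in cells of 3000 to 6000 UMIs (log2 ratio -0.091 against 1.67 over all cells). These 2 levels were close and have no interval here, so no difference in the other direction was shown. Ccl4 kept its direction in the 2 bands above, at 35.6 against 8.79 and 39.7 against 19.4 CPM.

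Numbers of genes past the size rule are given in the same order of comparisons. At low UMIs and after thinning fewer genes reach detection in 10% of cells, which by itself can lower these numbers. In cells of 3000 to 6000 UMIs they were 624, 122 and 989 in all T-like cells, 684 in CD8 T-like cells for OE against WT, and 883, 218 and 1206 in CD4 T-like cells. In cells of 6000 to 12000 UMIs they were 1031, 112 and 1342 in all T-like cells, with 1034 in OE against WT and 1452 in KD against OE in CD8 T-like cells. A pseudocount of 1 gave 127 in all, 186 in CD8 and 96 in CD4 T-like cells for KD against WT. A pseudocount of 25, which shrinks ratios of low genes by construction, gave 767, 14 and 1050 in all, 797, 22 and 1114 in CD8, and 883, 12 and 1069 in CD4 T-like cells. A threshold 1.5 times larger, which passes fewer genes by construction, gave 700, 12 and 987 in all, 754, 23 and 1103 in CD8, and 800, 10 and 1020 in CD4 T-like cells. After thinning they were 948, 32 and 1295 in all, 958, 60 and 1384 in CD8, and 994, 28 and 1254 in CD4 T-like cells. At the full depth of the libraries, 3-fold changes in simulated genes passed the size rule in 94%, 92% and 80% of cases.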

Other observations

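The test below was chosen only after the result was seen, and is given as values without an explanation. Of 1703 genes past the size rule in OE against WT, among 8301 genes detected in any library, 78.3% had the opposite sign in KD against WT. In 100 simulations with no change in KD the share averaged 39.0% and reached at most 40.7%, because both ratios share the WT library. The Pearson correlation of the 2 ratios across genes was -0.37, against 0.34 in the simulations, and the covariance -0.0864 against 0.000317. Genes are not independent replicates, and the single WT library cannot be split. Since the simulations had no change in KD, a difference between the KD and WT libraries of any source could exceed them. Median UMIs per cell also ran from 4720 in OE over 14851 in WT to 22484 in KD, and no share in cells of equal UMIs is given. Of genes past the rule in both ratios, 31 had opposite signs (6.92 expected) and 8 the same sign (6.62 expected). These expected numbers treat the 2 ratios as independent, which the shared WT library makes untrue, so they are not the values for no change. The share was 78.1% in CD8 and 69.1% in CD4 T-like cells, and 80.4% after thinning.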
